A study of Danio rerio with 12 samples.

How the data were processed

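Brains of 6-month-old male zebrafish were profiled by bulk RNA sequencing in 12 libraries, 4 from wild type and 4 from each of 2 transgenic lines that carry a miR-29 sponge. Per the labels' protocols, libraries were made from total RNA with the TruSeq RNA kit, version 2, which does not mark the strand. Reads from a gene and from an overlapping antisense partner therefore cannot be told apart in these counts. Per the submitters' processing notes, bcl2fastq 1.8.4, STAR 2.4.1d and featureCounts 1.4.6-p4 were used with genome build GRCz10; the annotation release is not given in the sources used here. How reads that match several paralogues were counted is not given either, so members of multigene families such as the MHC and finTRIM genes are uncertain.

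The authors deposited whole-number read counts per gene, and these counts were the input of every test below. The authors also deposited RPKM values for the same genes and libraries. The ratio of count to RPKM within a gene should follow the library total, which was checked over 6540 genes with more than 500 counts in every library. With each library's own total, the remaining coefficient of variation within a gene had a median of 0.179. With the 12 totals recycled down the genes it had a median of 1.48e-05 and a maximum of 0.000147. By that arithmetic, 8.33% of the deposited RPKM values were divided by their own library's total. RPKM recomputed with the right total differed from the deposited values by factors of 0.601 to 1.69, so the deposited RPKM values served only as an alternative setting.

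Groups were taken from the strain label of each sample. Replicate numbers follow accession order and pair no samples. The labels do not say whether the libraries of a group come from separate animals, so p-values measure only the spread between these libraries, which may be technical. Counts of replicate pairs differed by more than sampling noise (chi-square per degree of freedom 9.61 to 270), so no library was treated as a duplicate.

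Of 32105 gene identifiers, 26269 (81.8%) were paired with a symbol through the supplied name table, and 1632 symbols stand for more than 1 identifier. Such genes are printed with their identifier. Many symbols are those of the human orthologue, in capitals. Chromosomes came from a gene table of assembly GRCz12tu matched by symbol, from which no coordinates were taken. A gene without a match was placed on a chromosome only where its nearest matched neighbours in the count table lay on that same chromosome.

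Genes with more than 0.5 CPM (counts scaled to library size) in at least 4 libraries were tested (19645 genes, holding 99.9% of the counts). All 12 libraries entered 1 model with TMM normalisation, and each line was compared with wild type, and the lines with each other, by the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called higher or lower at an adjusted p under 0.05. Normalised CPM are given as mean ± SD of the 4 libraries of a group, and log2 fold changes with the standard error of the fit. Intervals (95%, exact binomial) and floors (3 counts over a group) cover counting error only.

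A total of 36 gene lists (reported miR-29 target classes, brain cell types, tissues that dissection could add, and stress or metabolic pathways) were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) at a preset inter-gene correlation of 0.01. List p-values were adjusted over all lists and both comparisons with wild type, and separately for the comparison between the lines. Of 985 listed symbols, 913 were matched. For each list the estimated correlation, fry, the number of members called, and the number called after adjustment over the list alone were computed as well. Tests for 3' UTR seed sites of miR-29 were planned and not run, since no genome sequence was used here.

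The groups, comparisons, gene lists, tests, alternative settings and the rule for naming genes were fixed before the data were examined. The rule took, per line and direction, up to 12 genes of largest log2 change among called genes with a true gene name, at least 2 CPM on average and all 4 libraries beyond those of wild type. It added up to 4 members of smallest p from each list described, a fixed set of genes tied to the constructs and to miR-29, up to 6 genes per direction between the lines, and the 10 best shared genes. Names with the clone prefix zmp were left out after the names were seen, under the rule's clause on similar prefixes.

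On simulated counts for the actb1 line against wild type (200 changed genes among 19645), edgeR recovered 20.9% of genes changed 1.5-fold, 50.7% changed 2-fold and 86.4% changed 4-fold, with 4 false calls. DESeq2 1.42.0 recovered 40.3%, 71.6% and 89.4% with 31 false calls, and limma 20.9%, 47.8% and 86.4% with 3. A further 40 genes were shifted by a log2 of 0.5 for the list test and were left out of the false calls.

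Alternatives were DESeq2, other scaling factors, other filters, fits of only the groups compared, limma on the RPKM values, 1 surrogate variable from sva 3.50.0, a threshold of 0.1, and leaving out each library in turn. Overlap between the lines was set against 20 simulations of all 12 libraries with no gene changed, in which both lines shared the same simulated wild-type group. Called genes were compared with 1e+05 random draws for closeness in the count table and for chromosome. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.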

Results

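The series compares brains of 6-month-old male zebrafish that carry a miR-29 sponge with brains of wild-type fish. A sponge is a transcript with binding sites for a microRNA, made to draw that microRNA away from its natural targets. One line is named for actb1, a broadly expressed cytoplasmic actin gene, and the other for kif5a, a kinesin heavy chain gene used in neurons. RNA was sequenced from 12 brain libraries, 4 of each group. Total gene counts per library ran from 2.09e+07 to 3.36e+07, and 23780 to 24354 genes had at least 1 count. The first 2 principal components of log2 CPM held 23.4% and 17.6% of the variance. Library actb1 sponge 3 stood apart in that protein-coding genes of the mitochondrial genome took 2.23% of its counts, against 9.20% to 13.7% in the other 11 libraries.

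Counts of the 2 namesake genes were close to wild type in both lines. The actb1 gene stood at 1116 ± 270 CPM in wild type (SD, n = 4) and differed by a log2 of 0.05 ± 0.18 in the actb1 line and 0.11 ± 0.18 in the kif5a line. KIF5A stood at 459 ± 61.3 CPM, with log2 differences of 0.23 ± 0.11 and 0.06 ± 0.11, and kif5ab at 57.6 ± 3.80 CPM with 0.13 ± 0.09 in each line. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the lowest adjusted p of these 6 comparisons was 0.311. The precursor genes MIR29A and MIR29B1 had at most 2 counts in any library and were not tested, so these libraries do not measure miR-29 itself.

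The first comparison asks how the actb1 sponge line differs from wild type. The deepest losses were those of mhc2dgb and mhc2dga, 2 neighbouring genes of the MHC class II family, which presents antigen. mhc2dgb stood at 19.8 ± 11.2 CPM in wild type and gave 1 count over the 4 sponge libraries, a ratio of 2340 (95% counting interval 420 to 92600). mhc2dga went from 13.9 ± 9.44 CPM to 2 counts, a ratio of 817 (226 to 6760). The list of interferon and antigen presentation genes was not called (32 tested, camera adjusted p = 0.975). cxcl12b, a chemokine gene, fell from 77.4 ± 15.4 to 19.8 ± 9.76 CPM, a log2 change of -1.97 ± 0.29. FAH, the last enzyme of tyrosine breakdown, fell by 2.09 ± 0.27 on the log2 scale, and znf106b by 1.89 ± 0.22. PRKAR2A (ENSDARG00000009477), a regulatory subunit of protein kinase A, rose from 3.64 ± 1.21 to 10.9 ± 1.03 CPM (log2 change 1.59 ± 0.24).

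In all, 55 genes were higher and 90 lower in the actb1 line among 19645 tested (0.738%; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 38 and 63 of them changed more than 2-fold. A further measure, complete separation of the 4 sponge from the 4 wild-type libraries, held for 9.33% of tested genes, against 2.86% by chance. dap1b (log2 change -8.83 ± 1.35), the finTRIM gene ftr12 (-3.09 ± 0.40) and the phosphatase gene DUSP22 (-1.91 ± 0.27) were also lower. Among named genes with at least 2 CPM on average, the largest increases were those of PDE6G, a phosphodiesterase subunit of rod photoreceptors (3.90 ± 0.80), CCDC134 (ENSDARG00000103285; 3.13 ± 0.61) and the lectin gene hbl2 (3.09 ± 0.57). The heat-inducible chaperone gene hsp70l rose by 1.73 ± 0.30. These increases were fragile: with each of the 8 libraries left out in turn, PDE6G was called in 1 fit, hbl2 in 1, CCDC134 in 2 (log2 changes of 2.71 to 3.77) and hsp70l in 4. The CPM of PDE6G was 47.0, 39.3, 23.1 and 4.84 in actb1 sponge 1 to 4 and 4.49, 22.8, 24.6 and 4.92 in kif5a sponge 1 to 4, highest in the 5 libraries that were also highest in other photoreceptor genes. PRKAR2A, mhc2dga, mhc2dgb, cxcl12b, FAH, znf106b, ftr12 and DUSP22 were called in all 8, and dap1b in 7. The count of higher genes was 20 without actb1 sponge 2 and 94 without wild type 3, and that of lower genes 32 and 156. DESeq2 called 449 higher and 485 lower.

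Reported miR-29 target classes moved little in the actb1 line. Of 30 tested matrix genes reported as miR-29 targets, 24 had a positive log2 change and the list was higher (median 0.18; camera of limma, Benjamini-Hochberg adjusted p = 0.0216, and adjusted p = 0.868 with an estimated correlation). Without actb1 sponge 3 its mean was 0.06 (adjusted p = 0.351) by camera, and the call was also lost without wild type 1. No member passed the test over all genes, and 1 did when adjusted over the list alone: LOXL3 (ENSDARG00000039563), a lysyl oxidase family gene, with a log2 difference of 0.83 ± 0.18. Of 24 collagen genes 21 were positive, with a median of 0.32 (camera adjusted p = 0.0733); col1a1a differed by 0.61 ± 0.50 and COL1A2 by 1.14 ± 0.52, and neither was called. The collagen list stood at 0.087, 0.092, 1.02 and -0.334 in actb1 sponge 1 to 4, with meninges and fibroblast genes at 0.116, 0.193, 0.428 and -0.051, and without actb1 sponge 3 col1a1a differed by 0.05 and COL1A2 by 0.46. The collagen list and the meninges and fibroblast list share col1a1a, COL1A2 and other collagen genes, so their likeness is partly built in. Of 34 other reported targets, 1 gene rose, LPL (ENSDARG00000087697), which encodes lipoprotein lipase, from 45.8 ± 3.60 to 91.3 ± 17.1 CPM, a call that held in 1 of 8 fits with a library left out. The count was 1 also when adjusted over the list alone, and the list had a median of -0.08 (camera adjusted p = 0.301). Genes of DNA methylation (12 tested, median -0.14, camera adjusted p = 0.142) and apoptosis (18 tested, median -0.22, camera adjusted p = 0.0535) did not pass as lists. Of the apoptosis genes, 0 were called over all genes and 2 were lower when adjusted over the list alone.

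Among 24 iron genes, SLC40A1, the cellular iron exporter ferroportin, fell from 83.4 to 53.7 CPM in the actb1 line (log2 change -0.64 ± 0.12; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0361) and was the 1 call also when adjusted over the list alone. That call held in 1 of the 8 fits with a library left out. IREB2, which encodes an iron regulatory protein, stood at 46.1 ± 1.56 CPM in wild type and differed by 0.14 ± 0.08 in each line, and was not called. The iron list as a whole had a median of 0.04, a mean of -0.01 and a camera adjusted p of 0.703. In the kif5a line no iron gene was called over all genes and 2 were lower when adjusted over the list alone, ISCU (ENSDARG00000035596; -0.37 ± 0.09) and SLC40A1 (-0.48 ± 0.12).

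Of the 36 lists, 11 passed camera in the actb1 line, all 11 with an adjusted p of 0.868 with an estimated correlation. Cholesterol synthesis genes were higher (22 of 26 positive, median 0.50; camera, Benjamini-Hochberg adjusted p = 0.000156) with no member called, also when adjusted over the list alone; HSD17B7 differed by 0.60 ± 0.23 and LSS by 1.03 ± 0.44. Genes of the circadian clock list were lower (30 of 35 negative, median -0.29; camera adjusted p = 2.26e-05) with no member called over all genes and 6 lower when adjusted over the list alone. cry-dash, a DASH cryptochrome gene outside that list, fell by 0.59 ± 0.12, a call that held in 0 of 8 fits with a library left out. Mitochondrial oxidative phosphorylation (46 genes, median 0.18, camera adjusted p = 9.22e-05) and cytosolic ribosome genes (52 of 53 positive, median 0.22, camera adjusted p = 0.00203) were higher, and both lost the call without actb1 sponge 4 (camera adjusted p = 0.123 and 0.107), where the mean of oxidative phosphorylation went from 0.18 to 0.11. Without actb1 sponge 3, the library low in mitochondrial transcripts, the ribosome mean was 0.00 (camera adjusted p = 0.842), and without actb1 sponge 2 it was 0.39. GABAergic neuron genes were lower (15 of 17 negative, median -0.31, camera adjusted p = 0.00808), as were immediate early genes (23 of 28 negative, median -0.21, camera adjusted p = 0.0139), and both lost the call without actb1 sponge 3 (camera adjusted p = 0.09 and 0.0565), where the GABAergic mean went from -0.30 to -0.17. The immediate early call was also lost without actb1 sponge 1 (camera adjusted p = 0.0712). Heat shock genes (22 of 28 positive, median 0.10, camera adjusted p = 0.0258) and oxidative stress genes (20 of 27 positive, median 0.14, camera adjusted p = 0.0336) were higher, calls that held in 5 and 4 of 8 fits with a library left out; the oxidative stress mean was 0.02 without actb1 sponge 3 and 0.21 without actb1 sponge 2. Among ependymal genes, RSPH4A, a radial spoke gene of motile cilia, rose by 1.17 ± 0.19 and was called in all 8 fits.

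Photoreceptor genes stood apart in some sponge libraries of both lines. GNAT1, the rod transducin gene, was 0.792 ± 0.892 CPM in wild type, and 44.1 ± 33.6 and 29.6 ± 32.3 CPM in the actb1 and kif5a lines. Relative to the wild-type mean, the list of 21 genes had mean log2 values of 3.91, 2.80, 3.85 and -0.29 in actb1 sponge 1 to 4, of -0.08, 3.58, 3.66 and 0.83 in kif5a sponge 1 to 4, and of -0.42 to 0.70 in wild type. The list was higher in the actb1 line (median 3.73; camera, Benjamini-Hochberg adjusted p = 4.99e-08) and in the kif5a line (median 3.38; camera adjusted p = 4.25e-06), with adjusted p = 0.868 with an estimated correlation in each. No member was called over all genes by edgeR, though PDE6G, a rod gene outside the list, was called in the actb1 line, and 16 and 14 members were higher when adjusted over the list alone. Skeletal muscle, skin and gill genes were also higher in the actb1 line (17 tested, median 0.69, camera adjusted p = 0.0258), a call that held in 4 of 8 fits with a library left out.

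**Figure D1:**
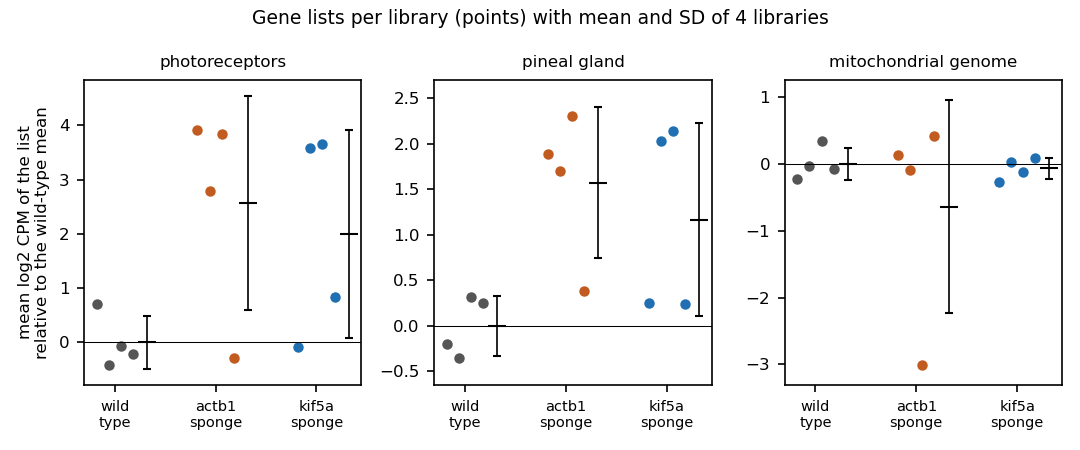
Mean log2 CPM of 3 gene lists relative to the wild-type mean, 1 point per library by group, with the mean and SD of 4 libraries beside the points. Photoreceptor and pineal genes are high in 5 of the 8 sponge libraries, at 2.80 or above for the photoreceptor list, and mitochondrial genome transcripts are at -3.01 in actb1 sponge 3.

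The second comparison asks how the kif5a sponge line differs from wild type, and its clearest group was the circadian clock. ciarta, a transcriptional repressor of the clock, fell from 41.3 ± 3.21 to 7.36 ± 1.09 CPM (n = 4 each), a log2 change of -2.49 ± 0.13. NR1D1, the nuclear receptor REV-ERB alpha that represses BMAL1, fell from 64.0 ± 13.6 to 12.9 ± 1.77 CPM (-2.31 ± 0.21). The period genes PER1 (ENSDARG00000056885; -2.01 ± 0.23) and PER2 (-1.03 ± 0.10) and the cryptochrome genes cry5 (-1.66 ± 0.16) and cry-dash (-1.85 ± 0.12; outside the fixed clock list, and called lower in both lines) fell as well. BMAL1 (ENSDARG00000006791), on the activating side of the loop, rose from 34.3 to 50.7 CPM (0.56 ± 0.09).

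Of 35 clock genes tested, 13 fell and 1 rose over all genes (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p from 2.05e-06 for ciarta to 0.0266 for CRY1, ENSDARG00000045768), and 15 and 5 when adjusted over the list alone. The list was lower (median -0.26, mean -0.44; camera, Benjamini-Hochberg adjusted p = 1.31e-08; adjusted p = 0.868 with an estimated correlation; fry adjusted p = 0.00417), with members on both sides. ciarta, NR1D1, PER2, cry5, cry-dash and both PER1 genes were called with any 1 of the 8 libraries left out. The 13 genes had mean log2 values of -1.42 to -1.09 in the 4 kif5a libraries, -0.35 to -0.18 in the actb1 libraries and -0.09 to 0.16 in wild type; the 13 were chosen by their calls in these same libraries. The labels used here give no time of sampling.

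**Figure D2:**
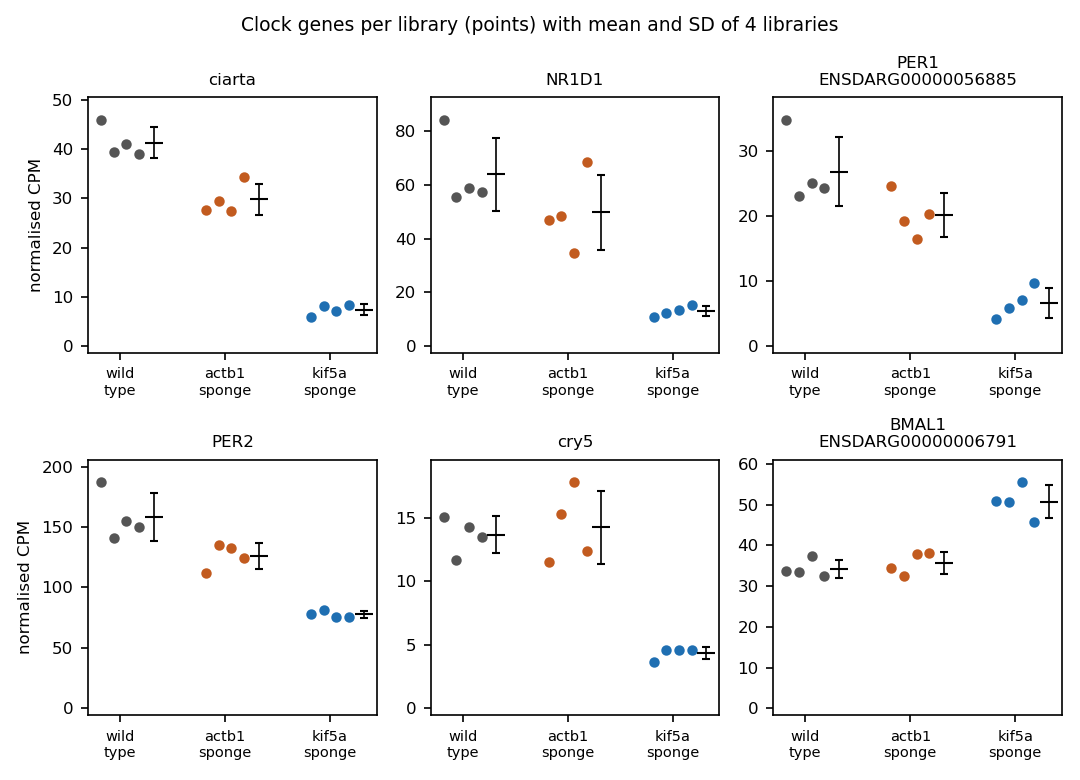
Normalised CPM (vertical axes, linear) of 6 clock genes in each library by group, with the mean and SD of 4 libraries beside the points. For ciarta all kif5a libraries lie near 7.36 CPM against 41.3 in wild type, while BMAL1 (ENSDARG00000006791) is higher in the kif5a line, at 50.7 against 34.3 CPM.

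Over all genes, 22 were higher and 83 lower in the kif5a line, the clock genes among them (0.534% of 19645; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 12 and 48 of them changed more than 2-fold. Complete separation of the libraries held for 9.24% of tested genes, against 2.86% by chance. armc9, a gene of the ciliary base, rose from 9.82 ± 0.775 to 33.7 ± 3.14 CPM (log2 change 1.78 ± 0.10) and rlf by 0.59 ± 0.09. mhc2dgb and mhc2dga had 0 counts in the 4 libraries, at least 787-fold and at least 549-fold lower than wild type at a floor of 3 counts over the group. PDK2 (ENSDARG00000059054), a kinase that inhibits pyruvate dehydrogenase, had a log2 change of -2.44 ± 0.40, ANGPTL4, an inhibitor of lipoprotein lipase, of -2.20 ± 0.36, and CPT1B, a carnitine palmitoyltransferase, of -2.03 ± 0.40. The complement regulator rca2.2 had a log2 change of -2.14 ± 0.31. COL12A1 (ENSDARG00000019601), a fibril-associated collagen gene, rose from 1.64 ± 0.714 CPM by 4.00 ± 0.66.

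With 1 library left out in turn, armc9, rlf, rca2.2, mhc2dga and mhc2dgb were called in all 8 fits, PDK2 and ANGPTL4 in 5, COL12A1 in 2 and CPT1B in 1. The count of higher genes was 5 without kif5a sponge 1 and 26 without wild type 3, and that of lower genes 30 and 70. Without the 5 libraries of high photoreceptor genes, which left 2 kif5a libraries, 5 genes were higher and 10 lower. DESeq2 on all libraries called 156 higher and 281 lower.

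Lists gave 8 calls in the kif5a line, each with an adjusted p of 0.868 with an estimated correlation. Cholesterol synthesis genes were again higher (24 of 26 positive, median 0.44; camera, Benjamini-Hochberg adjusted p = 6.74e-06), with SREBF1 at 0.82 ± 0.24 and no member called, also when adjusted over the list alone. The list stood at 1.14, 0.807, 0.009 and -0.286 in kif5a sponge 1 to 4, against -0.128 to 0.149 in wild type, so sponge 3 and 4 were not higher, and its mean went from 0.55 to 0.29 without sponge 1. Cytosolic ribosome genes were lower (52 of 53 negative, median -0.20; camera adjusted p = 2.67e-05). Microglia and macrophage genes were lower (25 of 28 negative, median -0.79; camera adjusted p = 0.000274), and 1 member fell, over all genes and when adjusted over the list alone: CTSB, the lysosomal protease cathepsin B, from 95.1 to 58.4 CPM (called in 5 of 8 fits with a library left out). Other leukocyte genes (median -0.72, camera adjusted p = 0.0373) and inflammation genes (median -0.55, camera adjusted p = 0.0258) were also lower. Wild-type libraries differed in these genes, with microglia list means of -0.84, 0.73, -0.82 and 0.94 in wild type 1 to 4. The microglia call was lost without wild type 4 (mean -0.36, camera adjusted p = 0.0653), and those of other leukocytes (mean -0.16, camera adjusted p = 0.566) and inflammation (mean -0.27, camera adjusted p = 0.434) without wild type 2, among other losses: the 2 calls held in 4 and 5 of 8 fits with a library left out. Without wild type 2 and 4, picked because they were highest in leukocyte genes, the 3 list means were 0.44, 0.28 and 0.33, a turn that this choice of libraries favours by construction.

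Of the reported miR-29 target classes in the kif5a line, collagens passed (19 of 24 positive, median 0.25; camera, Benjamini-Hochberg adjusted p = 0.0139; adjusted p = 0.868 with an estimated correlation), with no member called, also when adjusted over the list alone. The unadjusted edgeR p of col1a1a was 0.0249 and that of COL1A2 was 0.038, with 18.5 and 23.5 CPM in wild type and 45.2 ± 35.7 and 53.9 ± 41.3 CPM in the kif5a line. Without kif5a sponge 2 the collagen mean was 0.17 (camera adjusted p = 0.167). The collagen list stood at 0.336, 1.05, 0.248 and -0.02 in kif5a sponge 1 to 4, and the list of meninges and fibroblasts, cells rich in collagen, at 0.185, 0.758, 0.065 and -0.249 (not called, camera adjusted p = 0.333). Both lists hold col1a1a, COL1A2 and other collagen genes, so a like course is partly built in. Other matrix targets were centred on 0 (median 0.00, camera adjusted p = 0.908), and DNA methylation genes had a median of 0.15 (camera adjusted p = 0.258). Apoptosis genes had a median of -0.21 (13 of 18 negative, camera adjusted p = 0.0773). Of the other reported targets, 2 of 34 were called, also when adjusted over the list alone, both lower and both PER1 genes that the clock list holds too; the list had a median of 0.00, a mean of -0.16 and a camera adjusted p of 0.131.

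The third question is which genes both sponge lines share. A total of 23 genes were called in the same direction in both, 7 higher and 16 lower, and 0 in opposite directions (edgeR quasi-likelihood with Benjamini-Hochberg adjustment). mhc2dgb, mhc2dga, ftr12, znf106b and FAH were lower in both lines, and hsp70l, serpinb14, spef2, MAN2B2 and CCDC134 higher. hsp70l stood at 4.23 ± 1.52 CPM in wild type and at 14.0 ± 4.24 and 13.7 ± 4.42 CPM in the 2 lines. serpinb14 rose from 10.9 ± 2.30 to 22.6 ± 3.81 and 21.9 ± 0.801 CPM, and spef2, a gene of motile cilia and sperm tails, from 9.92 ± 1.35 to 21.0 ± 4.67 and 19.4 ± 2.63 CPM. DEF8 had log2 changes of -0.72 ± 0.11 and -0.69 ± 0.11. The uncharacterised genes ENSDARG00000100333 and ENSDARG00000099775 were lower and ENSDARG00000087767 higher in both lines with any 1 library left out. In the kif5a line the calls of hsp70l, spef2 and CCDC134 held in 2 of 8 such fits, that of MAN2B2 in 1, those of serpinb14 and FAH in 5, of ftr12 and DEF8 in 6 and of znf106b in 7. In the actb1 line that of DEF8 held in 7. With 1 library left out the count of shared genes was as low as 7, without kif5a sponge 3. DESeq2 called 144 genes in both lines, and without the 5 libraries of high photoreceptor genes edgeR called 3.

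The overlap has to be read beside the shared wild-type libraries. Independent lists of these sizes would share 0.442 genes. In 20 simulations of all 12 libraries with no gene changed, wild type simulated as well, 0 genes were shared. Each gene was drawn independently there, so shifts of many genes at once in a real wild-type library are absent. The simulation therefore cannot measure what such shifts add to the overlap or to the covariance. With the wild-type libraries split so that each line had its own 2, 7 to 15 genes were shared over 6 splits. Across genes, the log2 changes of the 2 lines had a correlation of 0.566 and a covariance of 0.214, against 0.503 and 0.0548 in the simulation, a covariance difference of 0.160. With split wild-type libraries the correlation was 0.175 to 0.477 and the covariance 0.0821 to 0.2. The sign was the same for 63.3% of genes, against 66.7% in the simulation. Genes are not independent replicates.

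**Figure D3:**
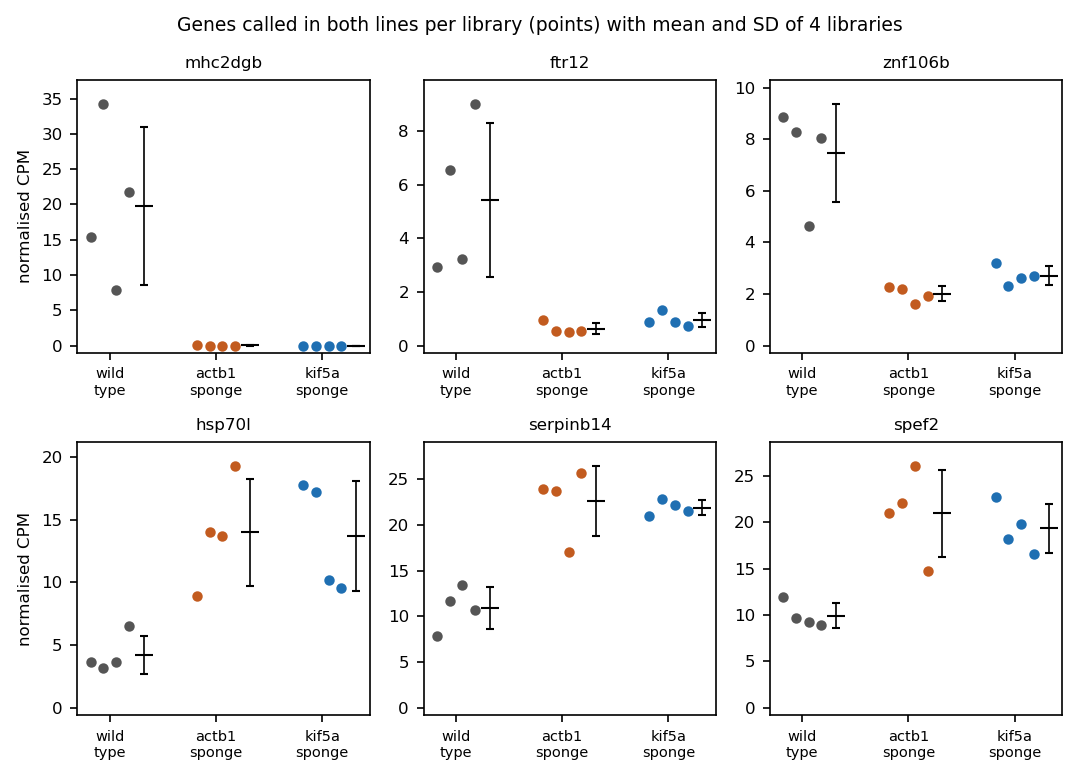
Normalised CPM (vertical axes, linear) of 6 genes called in both lines, 1 point per library by group, with the mean and SD of 4 libraries beside the points. mhc2dgb, ftr12 and znf106b are lower in both lines, and hsp70l (4.23 CPM in wild type against 14.0 and 13.7), serpinb14 and spef2 are higher.

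The 2 sponge lines were also compared with each other. This tests whether the lines differ, whether through the sponge or through anything else that sets them apart. There were 126 genes higher and 106 lower in the actb1 than in the kif5a line (232 of 19645, 1.18%; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), with complete separation for 10.4% of tested genes against 2.86% by chance. ciarta was higher in the actb1 line by 2.02 ± 0.13 and PDK2 (ENSDARG00000059054) by 2.64 ± 0.41, while armc9 (-1.96 ± 0.10) and ftr90 (-1.89 ± 0.25) were lower. KYAT3 (ENSDARG00000101791), a kynurenine aminotransferase gene, had 2 counts in the 4 actb1 libraries and 3.80 ± 2.78 CPM in the kif5a line, and it was called in 1 of 8 fits with a library left out. cox7a1, a cytochrome c oxidase subunit gene, was higher in the actb1 line by 2.29 ± 0.34, and that call, like those of ciarta, PDK2, armc9 and ftr90, held in all 8 fits. The count was 100 without kif5a sponge 2 and 177 without actb1 sponge 4, and DESeq2 called 950.

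Of the lists, 10 differed between the lines, none with an estimated correlation (adjusted p = 0.701 with an estimated correlation for each). All 53 ribosome genes had a positive difference (mean 0.42; camera, Benjamini-Hochberg adjusted p = 1.09e-11). That list stood at -0.147, -0.248, 0.749 and 0.278 in actb1 sponge 1 to 4 and at -0.318 to -0.079 in the kif5a libraries, so actb1 sponge 3, the library low in mitochondrial transcripts, and sponge 4 lay above the kif5a range and sponge 1 and 2 within it. Of the clock genes, 11 were higher and 4 lower in the actb1 than in the kif5a line, and 13 and 9 when adjusted over the list alone (median 0.12, camera adjusted p = 0.0401). Cell cycle genes were lower in the actb1 line (26 of 31 negative, mean -0.28, camera adjusted p = 0.000997), as were DNA methylation genes (10 of 12 negative, mean -0.31, camera adjusted p = 0.0124). The DNA methylation list stood at -0.081, -0.176, -0.071 and -0.527 in actb1 sponge 1 to 4 and at 0.041 to 0.227 in the kif5a libraries. Sponge 4 thus lay furthest from the kif5a range. Lists were not compared between the lines with a library left out.

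Called genes were unevenly placed in the genome. Each permutation p here is the share of draws in which the highest rate of calls on any chromosome was as high. Chromosome 4 held 17 of the 140 placed calls of the actb1 line (12.1%, against 3.90% of tested genes; permutation p = 0.00098 over 1e+05 draws), among them mhc2d4b. Many of these calls lay close together in the count table, and those were all lower. The draws took genes singly, so a stretch of neighbouring calls can by itself raise a chromosome's rate. Chromosome 18 held 9 of 103 placed calls in the kif5a line (8.74% against 3.18%; permutation p = 0.0391), and chromosome 22 held 29 of 226 between the lines (12.8% against 3.69%; permutation p = 1e-05, the smallest the draws can give). mhc2dga, mhc2dgb and ENSDARG00000101337 lie close together on chromosome 8. How reads that match several related genes were counted is not known here, so the single values of such genes are uncertain.

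**Figure D4:**
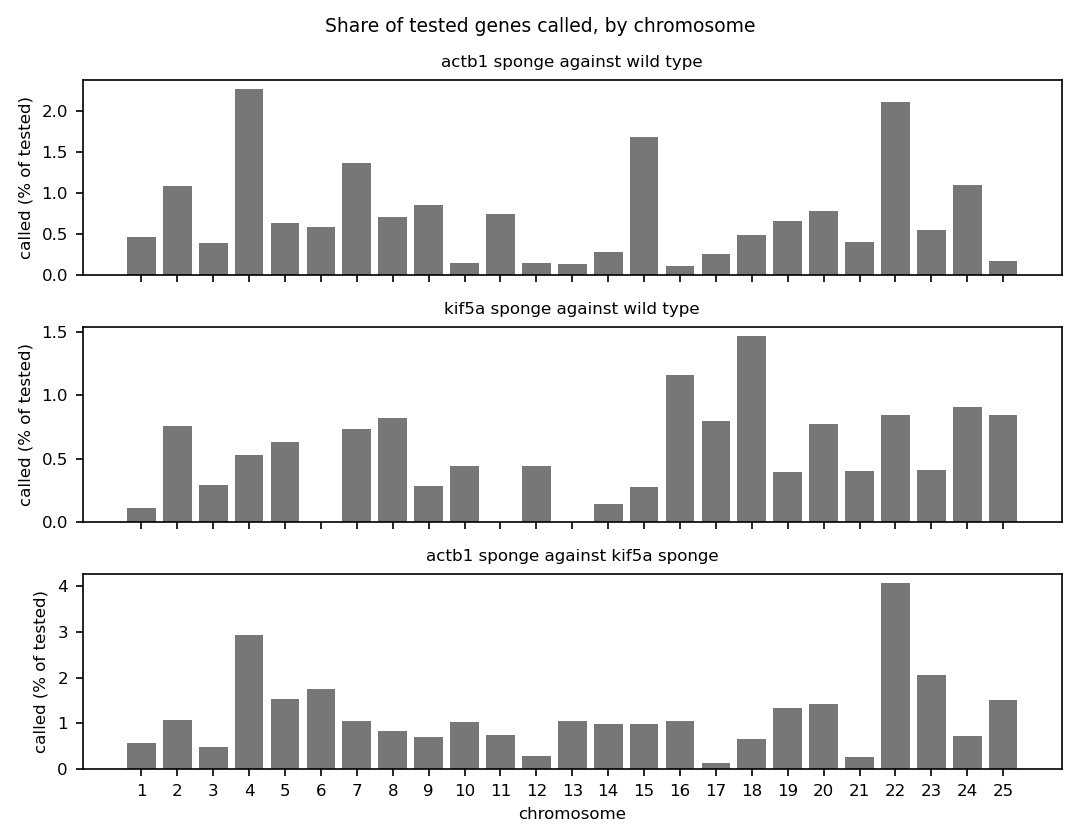
Called genes as a percentage of tested genes on each chromosome, 1 panel of bars for each of the 3 comparisons. The tallest bars hold 17 calls on chromosome 4 for the actb1 line, 9 on chromosome 18 for the kif5a line and 29 on chromosome 22 between the lines.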

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

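Both tests on the clock genes, and the test of a sponge effect on photoreceptor genes, were chosen after the result was seen. Over all 35 tested genes of the clock list, fixed before the data were examined, the kif5a libraries had mean log2 values of -0.549, -0.443, -0.407 and -0.365. Eye tissue in some libraries is argued against as the cause, since 4 of 4 lay below the lowest wild-type library (-0.063) while the photoreceptor list stood at 3.58 and 3.66 in kif5a sponge 2 and 3 and at -0.08 and 0.83 in kif5a sponge 1 and 4. In the kif5a line the activator arm had a median of 0.32 (camera unadjusted p = 0.000128, and p = 0.0633 with an estimated correlation) against -0.94 for the repressor and output arm. The activator arm held 11 BMAL, CLOCK, npas2, ROR and nfil3-5 genes, though nfil3-5 encodes a repressor. The other arm held 18 period, cryptochrome, NR1D, dbp, tef, ciart and BHLHE41 genes, which do not all encode repressors. All 13 clock genes called lower were among these 18. Another time of day or light at sampling could give such opposite arms. In the actb1 line both arms had medians below 0, -0.26 for the activator and -0.29 for the repressor and output arm, so opposite arms were not seen there. Since no label used here gives the time, sampling time and line cannot be told apart for these genes. An effect of the sponge on the clock was not tested apart from it.

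Photoreceptor genes were at 2.80 or above in 5 sponge libraries. An effect of the sponge in every library of both lines is argued against, since 2 of the 8 lay within the wild-type range. Pineal gland carried over at dissection is a candidate explanation: 4 pineal genes outside the photoreceptor list had a median of 0.93 in the actb1 line (camera unadjusted p = 0.0177, and p = 0.0503 with an estimated correlation), though the kif5a line did not pass (3 of 4 positive, median 0.84, p = 0.0645 and 0.112). Means of the pineal list were 1.89, 1.71 and 2.31 in actb1 sponge 1 to 3 and 2.04 and 2.15 in kif5a sponge 2 and 3. They were 0.385, 0.25 and 0.241 in the other sponge libraries and at most 0.312 in wild type. Among the 4 genes, ASMT changed most in the actb1 line (log2 change 5.83) and valopa least (0.01). A gene shared with the photoreceptor list was left out after the first result, a median of 1.33 over 5 genes in the actb1 line, had been seen. Retina carried over at dissection stays open: the other retinal and eye genes had a median of 0.30 in the actb1 line (camera unadjusted p = 0.645), but their list means were 0.496, 0.414, 0.857, 0.91 and 0.813 in the same 5 libraries, against -0.759, -0.021 and 0.09 in the other sponge libraries and at most 0.226 in wild type.

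Called genes lay close together in the count table: 42, 14 and 71 of the calls in the actb1 line, the kif5a line and between the lines had another within 5 tested genes, against means of 10.3, 5.44 and 25.9 in 1e+05 random draws. The share of draws as high was 1e-05 (the smallest possible), 0.0145 and 1e-05. Linked haplotypes that differ between the fish lines are a candidate explanation, and no biological one was tested. Named genes that had a called neighbour include DUSP22, hbl2, cry-dash, mhc2d4b and ftr90 in the actb1 line and armc9 in the kif5a line. In both lines they include mhc2dga, mhc2dgb, CCDC134 (ENSDARG00000103285), ENSDARG00000101337, ENSDARG00000087767, ENSDARG00000100333 and ENSDARG00000099775. Between the lines they include ciarta, slc26a10, PRKAR2A (ENSDARG00000009477), LPL (ENSDARG00000087697) and KYAT3 (ENSDARG00000101791). The same limit holds for all of these genes. In a further test, names with the clone or locus prefixes si, zgc, im, wu and LOC counted as lacking a symbol. Without pairs that share a symbol stem or lack a symbol in that sense the numbers were 0, 4 and 22. Only 33.3%, 50% and 45.1% of the called genes with a called neighbour have a symbol in that sense. Below 80%, a limit set after the result was seen, that test decides nothing, so reads shared between neighbouring paralogues cannot be told apart from other causes.

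With the 8 libraries of a comparison regrouped 4 against 4 in all 35 ways, the real grouping gave the most gene calls each time, 1 of 35: 145 against at most 54 in the actb1 line, 105 against 2 in the kif5a line and 232 against 3 between the lines. For genes called in both lines it was 1 of 60, 23 against 10. The 54 calls came from wild type 1 and 3 grouped with actb1 sponge 1 and 2. Wild type 2 and 4 lay close together on the first principal component (-47.4 and -46.9) and the second (-40.8 and -39.8). So did actb1 sponge 1 and 2 (35.48 and 35.47, then 3.29 and 4.21). The libraries of a group may therefore not be independent units, which the regroupings take them to be. List calls were as many or more in 24, 29 and 22 of the 35 groupings, the real one included: 11 against a highest of 18, 8 against 18 and 10 against 17. The number of lists called therefore does not set these groups apart from other groupings.

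Of 316 groups of 4 libraries, 26 (8.23%) held a library far from the other 3, where chance alone gives about 1 in 20. Wild type 2 had 24354 genes with a count. In list means relative to wild type, actb1 sponge 3 stood apart at -0.312 for neuronal cytoskeleton, -0.492 for oligodendrocytes, -3.01 for the mitochondrial genome and 0.461 for cholesterol synthesis. The other libraries set apart by a list were kif5a sponge 3 at 0.111 (oligodendrocytes), actb1 sponge 1 at -0.375 (skeletal muscle, skin and gill), wild type 1 at -0.091 (oxidative stress) and kif5a sponge 1 at -0.221 (p53 response).

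In log2 CPM of single genes, wild-type libraries far from their group were wild type 2 for hbl2 (1.23), ANGPTL4 (6.54) and tet3 (5.13), wild type 3 for cyp2p7 (2.88) and znf106b (2.24), and wild type 1 for NR1D1 (6.40) and adh8b (2.78). Of the actb1 libraries these were sponge 1 for mhc2dgb (-3.26), mhc2dga (-2.86) and ftr12 (0.0507), sponge 2 for rlf (6.09), sponge 3 for col1a1a (5.82) and COL1A2 (6.80), and sponge 4 for DNMT3A (ENSDARG00000005394; 2.50). Of the kif5a libraries these were sponge 2 for dap1b (-3.81) and sponge 4 for COL12A1 (ENSDARG00000019601, 1.52) and STXBP6 (3.89). For mhc2dgb and mhc2dga, actb1 sponge 1 held the only counts of that line, 1 and 2, so both flags rest on the count floor.

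The other values stand here because the 2 lines differed in the test of actb1 against kif5a, which called 232 genes. Higher in the actb1 line by log2 were cox7a1 (2.29), PRKAR2A (ENSDARG00000009477; 1.74), nepro (1.77), slc26a10 (1.97), TMEM117 (1.60), ciarta (2.02), PDK2 (ENSDARG00000059054; 2.64), NR1D1 (1.94), rca2.2 (2.25), PER1 (ENSDARG00000056885; 1.59), cry-dash (1.26), ldb3a (2.63), XYLB (2.12) and ENSDARG00000101337 (4.22). Lower were dap1b (-7.73), tnfrsf1b (-2.13), cxcl12b (-1.31), mhc2d4b (-1.79), COL12A1 (ENSDARG00000019601; -3.19), armc9 (-1.96), KYAT3 (ENSDARG00000101791; -7.47), adh8b (-1.95), abcc6a (-1.89) and ftr90 (-1.89). With each of the 8 libraries left out in turn, the call of tnfrsf1b between the lines held in 0 fits, those of ldb3a and KYAT3 in 1, and those of adh8b and abcc6a in 3.

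Of the lists, those with a higher mean in the actb1 than in the kif5a line were cytosolic ribosome (0.422), microglia and macrophages (0.482), skeletal muscle, skin and gill (1.05), circadian clock (0.205), oxidative phosphorylation (0.206), oxidative stress (0.183) and other matrix genes reported as miR-29 targets (0.145). Lower were DNA methylation (-0.308), GABAergic neurons (-0.29) and cell cycle (-0.281). All 10 had an adjusted p of 0.701 with an estimated correlation.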

How the results depend on the processing

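RPKM recomputed with each library's own total and the removal of 5 photoreceptor-high sponge libraries or of wild type 2 and 4 were chosen after seeing the data. Counts are given as higher and lower in the actb1 line, higher and lower in the kif5a line, between the lines, and in both lines; by edgeR they were 55, 90, 22, 83, 232 and 23. DESeq2 gave 449, 485, 156, 281, 950 and 144, all edgeR calls included, and a higher share of increases (48.1% against 37.9% in the actb1 line, 35.7% against 21.0% in the kif5a line). Deposited RPKM gave 30, 26, 21, 22, 115 and 13 with a pseudocount of 1, and 32, 29, 24, 27, 124 and 13 with 0.1. A threshold of 0.1 gave 175, 262, 35, 118, 582 and 46, by its construction. With only the 2 groups compared, the actb1 line had 35 and 46. RLE and upper-quartile factors, other filters, recomputed RPKM and 1 surrogate variable kept every count within 1.5 times.

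Without actb1 sponge 1 to 3 and kif5a sponge 2 and 3 the counts were 125, 454, 5, 10, 1117 and 3. This leaves the actb1 line 1 library, assumed to vary like the other groups, and 7 lists called there. Lists that reversed in the actb1 line were photoreceptors, with a mean of -0.917, a fall built in since the libraries were picked by this list, and immediate early genes, with a mean of -0.0665 that keeps its sign but lies on the other side of the remaining genes in camera. Without wild type 2 and 4 the actb1 line had 11 and 27 calls, the kif5a line 46 lower and both lines 12. There the kif5a means of microglia (0.44), other leukocytes (0.28) and inflammation genes (0.33) reversed, which the choice of the libraries highest in leukocyte genes favours by construction. Under both removals the clock list kept its calls in both lines and the cholesterol list in the kif5a line; in the actb1 line, with 1 library left, the cholesterol list was not called but its mean hardly moved (0.39 in both fits). With an estimated correlation 0 lists were called in each line, and with fry 0 and 1.

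Leaving out 1 library gave 20 (without actb1 sponge 2) to 94 (wild type 3) higher and 32 to 156 lower genes in the actb1 line, 5 (kif5a sponge 1) to 26 (wild type 3) and 30 to 70 in the kif5a line, 100 (kif5a sponge 2) to 177 (actb1 sponge 4) between the lines and 7 (kif5a sponge 3) to 25 (wild type 3) in both. Lists called were 6 (actb1 sponge 3) to 13 (actb1 sponge 1), and 6 (wild type 4) to 12 (kif5a sponge 4). Without actb1 sponge 3 the ribosome list of the actb1 line had a mean of 0.0028, still positive but on the other side of the remaining genes in camera (adjusted p = 0.842), the lowest of a range up to 0.392. Of the named calls, 16 of 39 genes in the actb1 line, 17 of 37 in the kif5a line and 7 of 12 between the lines held throughout, as did 3 of 11 and 4 of 8 lists. Apart from what construction gives, the cause was not tested. No paired analysis was possible because replicate numbers pair no samples. Alternatives on miR-29 seed sites were not run. Genes with more than 0.5 CPM in fewer than 4 libraries were not tested in the main fit, a limit set by the chosen filter. The setting without a filter on low counts tested those with any count.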

Other observations

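Beside CPT1B, ANGPTL4 and PDK2, these genes of fatty acid use were called lower in the kif5a line by edgeR quasi-likelihood with Benjamini-Hochberg adjustment over all genes: BBOX1 (-1.44), cpt1ab (-0.87), CROT (-0.65) and cyp4t8 (-0.65). They were chosen after their values were seen, so no test of the group is given. Their calls were not checked with a library left out. Of 24 tested genes listed for fatty acid oxidation and the fasting response, 8 were called lower and 4 had a positive log2 change in the kif5a line (median -0.34). Over all genes 83 of 19645 were called lower. The list holds CPT1B, ANGPTL4 and both PDK2 genes, so its count is partly built in. In the actb1 line 0 of the 24 were called (median -0.07, 9 positive). Uncalled falls there included BBOX1 (-1.01), PDK2 (ENSDARG00000020876; -0.97) and ANGPTL4 (-0.83).

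Pituitary genes varied between libraries. Relative to the wild-type mean, the list had mean log2 values of 0.743, -1.28, -0.217 and 0.757 in wild type 1 to 4, of 0.032, 1.21, 1.77 and 2.58 in actb1 sponge 1 to 4, and of -0.862, -1.07, 1.59 and -0.192 in kif5a sponge 1 to 4. Its 10 tested genes were not called as a list in either line (camera, Benjamini-Hochberg adjusted p = 0.142 and 0.783).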
